A study of Homo sapiens with 12 samples.

How the data were processed

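Total RNA was extracted with Trizol from LNCaP prostate cancer cells stably infected with a HOTAIR or a control lentivirus, grown in RPMI with 10% FBS. After 3 days of hormone deprivation the cells received ethanol or 1 nM R1881 for 24 h. Biotin-labelled RNA was hybridised to Illumina expression beadchips, 12 arrays in 4 groups of 3. Intensity values per probe, as deposited, were the authors' GenomeStudio signals before normalization, and were all positive and not on a log scale. Each signal came with a detection p-value per probe, deposited by the authors as GenomeStudio computed it from the negative controls of the array. The authors also deposited a processed intensity per probe. From the values these were background subtracted, some being below 0, and brought to a shared distribution within replicate 1 and, apart from it, within replicates 2 and 3. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. All columns of per-sample values were used, leaving 0 aside.

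Probes were paired with genes through the annotation of the array platform, and gene names were matched by Entrez ID to those of a RefSeq table of human genome build 38. Of 47316 probes, 30110 had 1 gene, 8 had several and 17198 were not listed. Of 30118 listed probes, 30071 had an Entrez ID in the RefSeq table and 0 symbols needed an update. The probes with 1 gene covered 20044 genes. A pair of genes in the rule for named genes have no probe in the annotation used and were not analysed here.

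Signals were background corrected with the normexp model, with the background estimated from the detection p-values (limma neqc, offset 16), then quantile normalized and put on the log2 scale. A probe was kept if its detection p-value was under 0.05 on the 3 arrays of at least 1 group, which left 17297 probes, 13495 of them with 1 gene and 3802 without. Where a gene had several detected probes (2542 genes) the probe with the highest mean was used, giving 10397 genes. Probes detected per array ranged from 17848 to 20015, and correlations between arrays from 0.9404 to 0.9938. Signal over background limits the genes near the detection limit, and 3 arrays per group leave 8 residual degrees of freedom.

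The design was fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group, the variance of each gene moderated with a trend on mean level, and Benjamini-Hochberg adjusted p under 0.05 over all genes in each contrast. The 5 contrasts were HOTAIR against control in ethanol and in R1881, R1881 against ethanol in control and in HOTAIR cells, and the interaction, the difference of the R1881 responses. Every adjusted p of a gene in the report is from limma's moderated test. Where a group was undetected on its arrays a fold is given as a lower bound. The values of that group's arrays were raised to the lowest normalized value among detected probes of the same array where they lay below it, and the difference of the log2 group means was taken as a fold.

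Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. The same test with the correlation estimated from the data, and fry, were run beside it. Of 20 lists, 17 had at least 5 measured members and were tested. They were androgen-induced and androgen-repressed genes, cholesterol and fatty acid synthesis, endoplasmic reticulum folding and unfolded protein response, S phase and DNA replication, mitosis, PRC2 and LSD1-CoREST components, the HOXC cluster, the HOXD cluster with other published HOTAIR targets, and epithelial-mesenchymal transition and invasion. The others tested were the type I interferon response, hypoxia and glycolysis, p53 targets, oxidative phosphorylation, luminal prostate identity, markers of prostate lines without an androgen response, and housekeeping genes. Neuroendocrine, basal and stromal markers had 4, 1 and 3 measured members and are given as counts. Some genes stand in several lists. Counts of members past the test are given over all genes and adjusted over the list alone. They come from the fit without a block unless the batch as a block is named.

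Genes named in the report followed a rule. It took a fixed set of androgen-response genes and HOTAIR. In each simple contrast it took the 8 largest increases and the 8 largest decreases past the threshold whose 3 arrays of 1 group all lay above the 3 of the other. In the interaction it took the 5 largest of each sign, and for each list the 2 to 4 members with the largest change past the threshold, or else the member with the smallest p. Lists, contrasts, tests, named genes and most alternatives were chosen before the data were examined.

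The arrays of replicate 1 differed from those of replicates 2 and 3 in every group, and the authors' processed values of the former had been normalized apart from the latter. The labels give no batch, so this batch of 4 against 8 arrays is inferred from the values. It took 69% of the sum of squares within groups, and 5788 genes (55.7%) differed between the batches. To see whether replicate numbers pair the cultures, values centred on their group were correlated between groups. Correlations for the same number were 0.758 to 0.805 (replicate 1), 0.435 to 0.553 (replicate 2) and 0.43 to 0.53 (replicate 3). Those of replicate 2 with replicate 3 were 0.368 to 0.5, and those of replicate 1 with the others -0.649 to -0.539. The difference of replicates 2 and 3 correlated by -0.0131 to 0.0904 between groups. The pairing thus came from the batch, and the batch was added as a block in an alternative fit, with the replicate number as another.

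The fit was tested on simulated data with the spread and batch of these arrays, 10397 genes of which 200 were changed between HOTAIR and control cells in ethanol by 1 or 0.5, and 30 others, taken as a list, by 0.3. Without a block it recovered 75 of 100 genes with a log2 change of 1 and 12 of 100 with 0.5, with 0 false calls. With the batch as a block it recovered 98 and 63, with 8 false calls among 173, the remaining calls being genes of the shifted list. In unchanged contrasts 0 genes were called by either fit. In the camera test of limma without the block, the list shifted by 0.3 passed and an unchanged list did not. The noise was drawn independently for each gene, so this does not test lists whose genes vary together. The estimated correlation of the androgen-induced list, for example, was 0.217.

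Relations between contrasts were correlations of log2 fold changes across genes. For contrasts that share control arrays, 200 simulations of unchanged groups gave the reference.

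The alternatives tried were no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed values, a detection p under 0.01 on all arrays, no detection filter, all probes, the mean of a gene's probes, a replicate block, only the groups compared, array weights, moderation without the trend, each array left out in turn, an estimated correlation between genes and fry. The batch as a block, replicates 2 and 3 only, replicate 1 alone, and the authors' processed values with the batch as a block were added after the data were seen. Fits with an array left out had no block for the batch. Each such fit leaves the batch uneven between the groups, so a lost call or a lower count can come from that unevenness. A block by slide was not run, because the files name no slides. Probes without a gene entered no count of genes and are given as counts in the closing section. Figures were drawn with matplotlib 3.10.9 from tables handled in pandas 2.3.3 under python 3.11.15.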

Results

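Gene expression was measured in LNCaP cells, an androgen-responsive line derived from a lymph node metastasis of prostate cancer. Cells stably infected with a lentivirus carrying the long non-coding RNA HOTAIR (HOTAIR cells) were set beside cells infected with a control lentivirus (control cells). Both were kept without hormone for 3 days and then given either the ethanol vehicle or 1 nM R1881, a synthetic androgen, for 24 h. The 4 groups held 3 arrays each, 12 in all. The labels call the arrays of a group biological replicates, but do not say whether they came from separate infections. Between 17848 and 20015 of 47316 probes were detected per array, and 10397 genes entered the tests. The median signal of an array was 105.1 to 107.6 for the 4 arrays of replicate 1 and 89.8 to 93.8 for the 8 arrays of replicates 2 and 3. The number of arrays limits the precision of every fold change given here.

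HOTAIR itself separated both lines. The lncRNA, transcribed from within the HOXC cluster and known for binding chromatin-modifying complexes, was detected on every array of HOTAIR cells and on no array of control cells. Its mean signal in ethanol was 578.2 ± 131 (SD, n = 3) in HOTAIR cells and 94.33 ± 8.31 in control cells. In R1881 the corresponding signals were 774.7 ± 144 and 90.4 ± 8. Because control cells lay at background, the difference is a lower bound. Against the dimmest detected signals of the control arrays, HOTAIR was at least 18.2-fold higher in ethanol (adjusted p = 1.21e-08) and at least 26.7-fold higher in R1881 (adjusted p = 2.24e-09). The other HOTAIR probe on the array gave bounds of 12.5-fold and 19.8-fold. Within HOTAIR cells, R1881 raised the transcript by a log2 fold change of 0.55 (adjusted p = 0.0437). That call was lost with median scaling (adjusted p = 0.117) and in the authors' processed values (0.147).

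**Figure D1:**
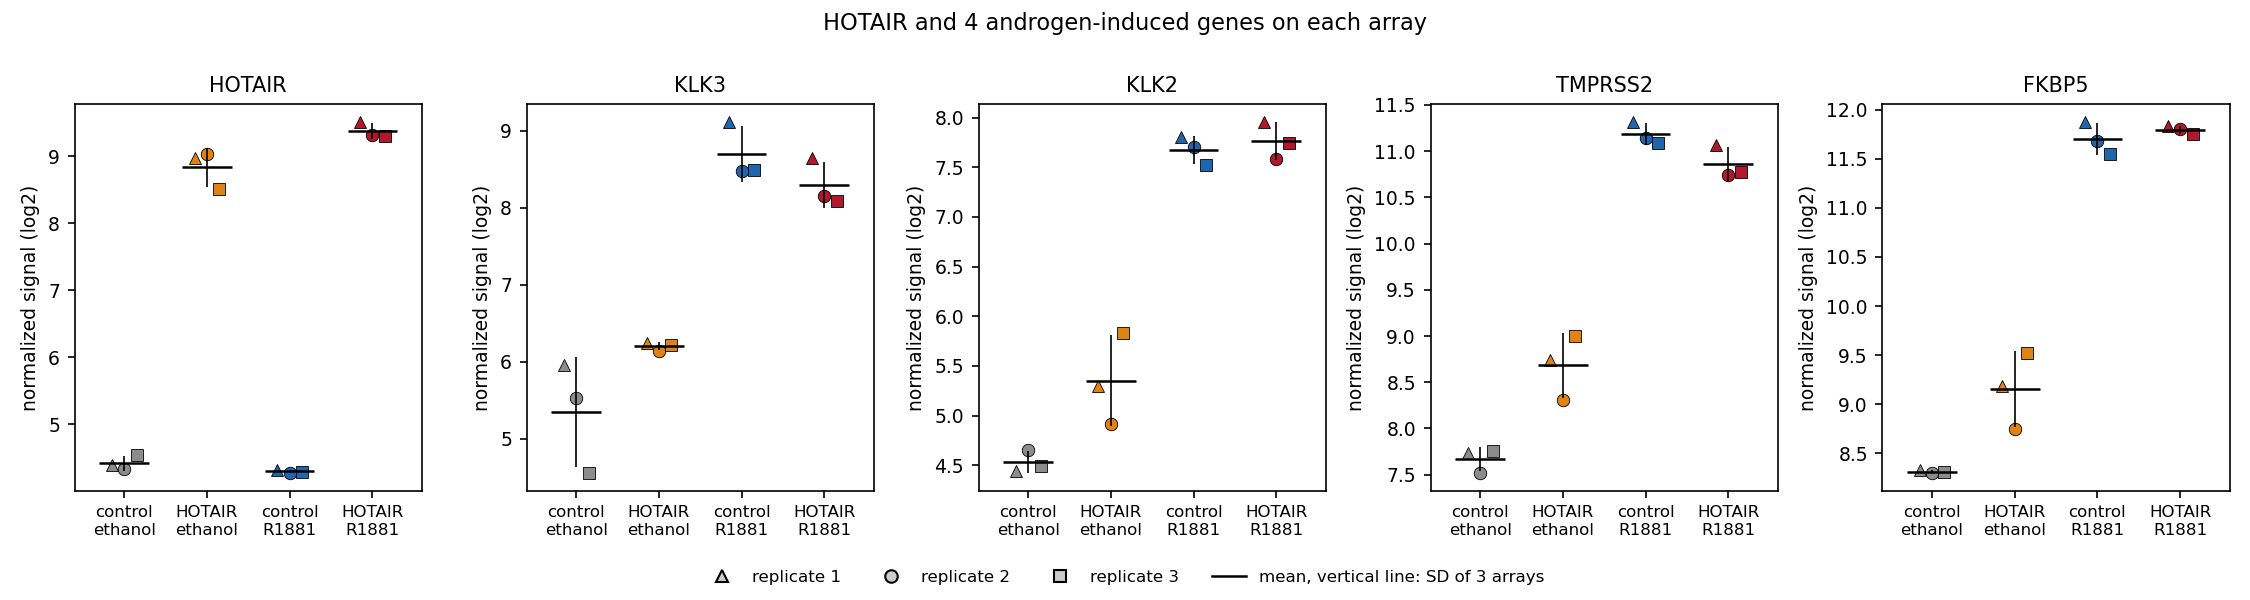
Normalized log2 signal of HOTAIR and 4 androgen-induced genes (y axes) in the 4 groups (x axes); symbols are single arrays by replicate number, horizontal lines the group means and vertical lines the SD of 3 arrays. HOTAIR is near 4.4 in control cells and 8.8 to 9.4 in HOTAIR cells, and the 4 androgen-induced genes are higher in R1881 than in ethanol in both lines.

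The comparison of HOTAIR with control cells in ethanol asks what HOTAIR changes when no androgen has been added. The androgen-induced and mitosis lists were shifted upward in HOTAIR cells and the HOXC list downward. In the list test with the batch as a block and an estimated correlation, the androgen-induced and HOXC calls were lost (adjusted p = 0.0886 each). The mitosis list lay at the threshold there (adjusted p = 0.05). TMPRSS2, an androgen-regulated serine protease, rose by 1.01 on the log2 scale (SE 0.16, adjusted p = 0.0116), and FKBP5, a co-chaperone of steroid receptors, rose by 0.84 (SE 0.16, adjusted p = 0.0244). KLK3, which encodes prostate-specific antigen, had a log2 difference of 0.86 that did not pass the test (adjusted p = 0.27, and 0.00163 with the batch as a block). It was undetected on replicate 3 of the control cells, where its log2 signal was 4.551, against 5.954 and 5.529 on replicates 1 and 2. KLK2, a related kallikrein, was undetected in control cells in ethanol and was at least 1.62-fold higher in HOTAIR cells, also not past the test (adjusted p = 0.0811; 0.00154 with the block).

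The largest increases beside HOTAIR were in TM4SF1, a surface protein of the tetraspanin-like family (1.80 on the log2 scale, SE 0.32), and AKR1C4, an aldo-keto reductase of steroids (1.69). TARP, a transcript of the T-cell receptor gamma locus made in prostate cells, and IFIT1, an interferon-induced RNA-binding protein, each rose by 1.41. UGT2B10, a glucuronosyltransferase, rose by 1.33, CES1, a carboxylesterase, by 1.28 and PIP, a secreted prolactin-inducible protein, by 1.22. The largest decreases were in CBLN2, a synaptic organiser (-1.96), CACNA1H, a T-type calcium channel subunit (-1.75), and PEG3, an imprinted zinc finger gene (-1.57). MDK, a heparin-binding growth factor, changed by -1.39. The prostate-expressed olfactory receptors OR51E1 and OR51E2 changed by -1.39 and -1.34, and the X-linked testis genes VCX3A and VCX3B by -1.30 each. VCX3A and VCX3B are near-identical paralogs, so their probes need not be independent.

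Among the gene lists, 34 members of the androgen-induced list were measured. In HOTAIR cells in ethanol 7 rose and 0 fell over all genes tested, and adjusted over the list alone 17 rose and 0 fell. With the batch as a block 20 rose and 0 fell over all genes. The list's mean shift was 0.49 on the log2 scale (adjusted p = 1.25e-17; adjusted p = 0.0421 with an estimated correlation), 0.45 in replicate 1 and 0.52 in replicates 2 and 3. This call was lost with the batch as a block and an estimated correlation (adjusted p = 0.0886). Beyond TMPRSS2 and FKBP5, the members with the largest increases were NDRG1, a stress-responsive gene (1.05), and ABCC4, a transporter that exports cyclic nucleotides (0.84). All 29 measured mitosis genes had positive differences, with a mean of 0.40 (adjusted p = 1.25e-17; adjusted p = 0.0166 with an estimated correlation and 0.05 with the batch as a block besides; 0.45 in replicate 1 and 0.37 in replicates 2 and 3). With the batch as a block 19 of these rose over all genes and 0 fell. Without it 3 rose over all genes and 13 adjusted over the list alone. Among them were the kinase AURKA (0.62), the anaphase activator CDC20 (0.58) and the ubiquitin-conjugating enzyme UBE2C (0.45). The 5 measured HOXC genes shifted by a mean of -0.47 (adjusted p = 9.31e-06; adjusted p = 0.0421 with an estimated correlation, lost at 0.0886 with the batch as a block besides; -0.51 in replicate 1 and -0.45 in replicates 2 and 3). HOXC9 was the single member that fell over all genes (-0.62, adjusted p = 0.0462), and 4 fell adjusted over the list alone. With the batch as a block 4 fell over all genes and 0 rose. The HOXC9 call was lost with median scaling (adjusted p = 0.157) and in replicates 2 and 3 alone (adjusted p = 0.115).

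Smaller upward shifts in ethanol passed the list test for endoplasmic reticulum folding genes (mean 0.18, adjusted p = 0.12 with an estimated correlation), of which 0 of 23 passed singly, and for S phase genes (mean 0.19, adjusted p = 0.087 with an estimated correlation), of which 0 of 26 passed and 1 rose adjusted over the list alone. With the batch as a block 5 folding genes were higher and 1 lower, and 9 S phase genes were higher and 0 lower. The interferon list had a mean of 0.18 (adjusted p = 0.0404, and 0.522 with an estimated correlation), with IFIT1 and IFIT2 (1.10) the 2 members that rose. Adjusted over the list alone 7 rose and 1 fell, and with the batch as a block 8 of its members were higher and 2 lower. With a detection p under 0.01 on all arrays its mean was 0.06 (adjusted p = 0.691). Its call was also lost with median scaling (adjusted p = 0.106), in replicates 2 and 3 only (0.0636) and without single arrays in ethanol: replicate 1 of the control cells (adjusted p = 0.347), replicate 2 of the control cells (0.0643) or of the HOTAIR cells (0.0881), or replicate 3 of the HOTAIR cells (0.105). The hypoxia list had a mean of 0.11 (adjusted p = 0.0404; adjusted p = 0.234 with an estimated correlation), although ADM, a vasodilator peptide and the one member past the test, fell by 0.89. Without replicate 1 of the HOTAIR cells the hypoxia mean was 0.06 (adjusted p = 0.206), without replicate 2 of the control cells 0.06 (0.222) and without replicate 3 of the control cells 0.12 (0.0635). The hypoxia call was also lost with no background correction (adjusted p = 0.071), an offset of 50 (0.0552), median scaling (0.0553), the authors' values (0.0631), the mean of probes (0.0606) and moderation without the trend (0.0718).

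Androgen-repressed genes in ethanol moved in opposite directions. The glucuronosyltransferases UGT2B28 (1.02) and UGT2B11 (0.83) rose while PEG3 and DDC, the aromatic amino acid decarboxylase (-0.77), fell. The mean of -0.17 did not pass the list test (adjusted p = 0.178). Despite the name of the list, UGT2B28 and UGT2B11 were also raised by R1881 in control cells (1.97 and 1.16).

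Other lists were not past the test in ethanol. Of 13 measured PRC2 and LSD1-CoREST components, the complexes HOTAIR is known to bind, 0 changed and the mean was -0.01 (adjusted p = 0.815). For the HOXD cluster and other published HOTAIR targets, 5 members were measured. They were CDKN1A, EPHA1, HOXD3, LAMB3 and PCDHB5, so HOXD3 alone stood for the HOXD cluster. The mean was -0.15 and the median 0.05, of opposite signs, and the adhesion gene PCDHB5 had a difference of -0.86 (adjusted p = 0.0502; 3.03e-05 with the batch as a block). VIM, a mesenchymal filament protein, rose by 0.85, the 1 gene of 12 that changed in the epithelial-mesenchymal list (mean 0.13, adjusted p = 0.371). VIM is also a marker of prostate lines without an androgen response; in that list VIM rose and the chemokine CXCL8 fell by 0.75, and the mean was -0.02 (adjusted p = 0.848). Of the 4 measured neuroendocrine genes, too few to test as a list, the tubulin TUBB3 fell by 0.85. SESN1, a stress-response gene, fell by 0.58 in the p53 list (mean -0.10, adjusted p = 0.0843); with median scaling its adjusted p was 0.282. Means were 0.05 for cholesterol and fatty acid synthesis (adjusted p = 0.561), 0.08 for oxidative phosphorylation (0.178), 0.03 for luminal identity (0.819, with a test direction opposite to the mean) and 0.11 for housekeeping genes (0.0843). In these 4 lists 0 genes changed without a block, and some members of each passed with the batch as a block.

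Over all genes, 63 were higher and 73 lower with HOTAIR in ethanol, 19 and 17 of them by at least 2-fold. With the batch as a block the counts were 623 and 620, and all 136 genes kept their call and sign; with the replicate number as a block 1334 genes were called, and in replicates 2 and 3 alone 507, 130 of the 136 among them. Median scaling, under which the median log2 fold change of all genes was 0.137 instead of 0.00535, gave 78 higher and 28 lower, so the balance of the directions rests on the scaling. Leaving out single arrays lowered the count to between 34 (without replicate 2 of the control cells or replicate 3 of the HOTAIR cells) and 86. Each omission also left the batch uneven between the groups, with no block for it.

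**Figure D2:**
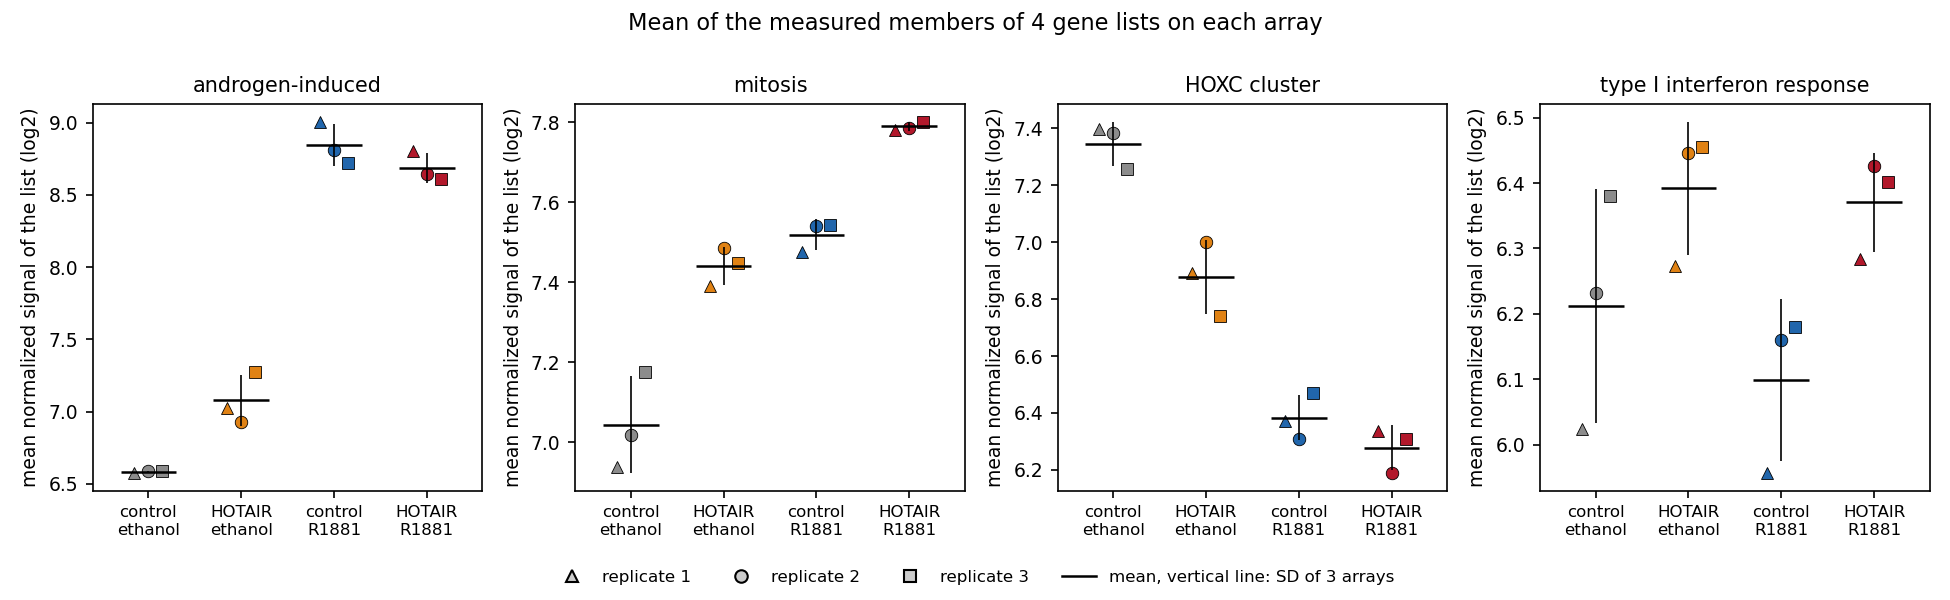
Mean normalized log2 signal (y axes) of the measured members of 4 gene lists on each array, by group (x axes); symbols mark the replicate number, horizontal lines the group means and vertical lines the SD of 3 arrays. The androgen-induced list is higher in HOTAIR than in control cells in ethanol on all 3 replicates, by a mean of 0.49, and not in R1881, where the mean difference is -0.16.

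With androgen present, the same comparison asks what HOTAIR changes in stimulated cells. AKR1C4, CES1, UGT2B10, PIP, IFIT1 and IFIT2 were higher as in ethanol and PEG3, MDK and CACNA1H lower, and no member of the androgen-induced list rose. The differences in KLK3 (-0.40, adjusted p = 0.858), TMPRSS2 (-0.32, adjusted p = 0.622), KLK2 (0.09, adjusted p = 0.992) and FKBP5 (0.09, adjusted p = 0.987) did not pass the test. The largest increases beside HOTAIR were in AKR1C4 (1.79, SE 0.34), CES1 (1.64) and IGFBP3, a binding protein of insulin-like growth factors (1.60, SE 0.17, adjusted p = 0.000891). PIP rose by 1.57, UGT2B10 by 1.48, the zinc finger gene ZNF121 by 1.45 and IFIT2 by 1.39. The largest decreases were in PEG3 (-1.83), HINT3, a nucleotide hydrolase (-1.64), CACNA1H (-1.52) and ANGPT2, an angiogenic ligand (-1.52). MDK changed by -1.46, the Notch ligand JAG1 by -1.46, the focal adhesion gene PARVA by -1.40 and the proteoglycan SPOCK1 by -1.36. SPOCK1 lost its call with median scaling (adjusted p = 0.0763).

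In R1881 the androgen-induced list had a mean of -0.16 (adjusted p = 0.00257; adjusted p = 0.432 with an estimated correlation), -0.21 in replicate 1 and -0.14 in replicates 2 and 3. SPOCK1 was its 1 member that fell and 0 rose, over all genes and adjusted over the list alone. With the batch as a block 7 members fell and 0 rose over all genes. Without replicate 1 of the control cells the mean was -0.08 and no longer past the test (adjusted p = 0.186). That omission leaves the batch uneven between the lines, and the value lies outside those of replicate 1 and of replicates 2 and 3. In the interferon list IFIT2 and IFIT1 (1.21) rose over all genes and 5 adjusted over the list alone. With the batch as a block 7 of its members were higher and 1 lower. The mean was 0.27 (adjusted p = 9.7e-05; adjusted p = 0.432 with an estimated correlation), 0.33 in replicate 1 and 0.24 in replicates 2 and 3. With a detection p under 0.01 on all arrays the interferon mean was 0.15 and not past the test (adjusted p = 0.0923). The mitosis list had a mean of 0.27 with 28 of 29 differences positive (adjusted p = 1.05e-09; adjusted p = 0.0953 with an estimated correlation). Among its members 0 passed over all genes and 1 adjusted over the list alone, and CDC20 had the smallest p (0.48, adjusted p = 0.0887). With the batch as a block 10 mitosis genes were higher over all genes and 0 lower. The folding list had a mean of 0.18 (adjusted p = 3.75e-05, and 0.232 with an estimated correlation) with 0 members past the test and 4 higher adjusted over the list alone. With the batch as a block 5 folding genes were higher and 0 lower. Shifts of -0.12 in p53 targets (adjusted p = 0.0365) and 0.10 in oxidative phosphorylation (adjusted p = 0.0206) both had an adjusted p = 0.432 with an estimated correlation, and 0 of their members passed over all genes. With the batch as a block 2 p53 targets were lower and 0 higher, and 2 oxidative phosphorylation genes were higher and 0 lower. The call for p53 targets was lost without replicate 1 of the HOTAIR cells (-0.07, adjusted p = 0.194) and without replicate 3 (-0.08, 0.187) or 2 (-0.12, 0.0554) of the control cells, with median scaling (0.0672) and with a detection p under 0.01 on all arrays (0.0566). That for oxidative phosphorylation was lost without replicate 1 of the control cells (0.03, adjusted p = 0.186) and without replicate 3 of the HOTAIR cells (0.07, 0.0671).

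Among androgen-repressed genes in R1881, UGT2B28 (1.10), UGT2B17 (1.04) and IGFBP3 were among 4 that rose, and PEG3 was the 1 that fell; the mean was 0.08 and the median -0.17, of opposite signs (adjusted p = 0.415). PCDHB5, a published HOTAIR target, fell by 1.02 (adjusted p = 0.0336), the 1 change among 5 measured targets, whose mean of -0.18 and median of 0.05 also differed in sign (adjusted p = 0.46). Its call was lost with median scaling (adjusted p = 0.078). Among 3 measured stromal genes, too few to test, the smooth muscle actin ACTA2 rose by 0.96. Means not past the test, in lists with 0 genes changed without a block, were -0.11 for the HOXC cluster (adjusted p = 0.304), 0.10 for S phase (0.0881), 0.02 for PRC2 and LSD1-CoREST components (0.762), -0.10 for hypoxia (0.0881) and -0.06 for cholesterol and fatty acid synthesis (0.264). Those for the epithelial-mesenchymal list (-0.02), luminal identity (-0.04), lines without an androgen response (0.03) and housekeeping genes (0.02) each had an adjusted p of 0.762, and the 4 neuroendocrine genes gave -0.26 with 0 past the test. Some members of these lists passed with the batch as a block. Among them 4 S phase genes were higher and 0 lower, and 2 cholesterol and fatty acid synthesis genes were higher and 6 lower.

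With HOTAIR in R1881, 31 genes were higher and 33 lower, 13 and 19 by at least 2-fold. The batch block gave 418 and 476, among them all 64 genes with the same sign, the replicate block 1007 and replicates 2 and 3 alone 280. Median scaling gave 29 higher and 18 lower, and leaving out single arrays between 26 and 36 genes.

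Effects of HOTAIR in ethanol and in R1881, which share no array, were correlated across the 10397 genes (Pearson r = 0.56, Spearman 0.468; r = 0.485 in replicates 2 and 3). Genes are not independent replicates, so no p-value is attached. Both contrasts compare the same infected lines, so a lasting difference between the lines would recur in both, whether or not HOTAIR caused it. Of the genes called, 18 were higher and 22 lower in both treatments, where independence would give 0.188 and 0.232, and 0 had opposite signs. CACNA1H, PEG3 and MDK were lower in both, and HOTAIR itself, AKR1C4, CES1, UGT2B10, PIP, IFIT1 and IFIT2 higher in both.

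R1881 against ethanol in control cells asks which genes the androgen moves without added HOTAIR. The androgen-induced and mitosis lists were shifted upward and the HOXC list downward, each also with an estimated correlation. TARP rose by 4.26 on the log2 scale (SE 0.14, adjusted p = 1.3e-08), TMPRSS2 by 3.51 (SE 0.16), FKBP5 by 3.39 (SE 0.16), the signalling inhibitor ERRFI1 by 3.37 and KLK3 by 3.35 (SE 0.30, adjusted p = 1.41e-05). The KLK3 value includes the array of control cells in ethanol on which it was undetected. Several genes were undetected in ethanol. HPGD, which degrades prostaglandins, was at least 10.9-fold higher, PGC, a pepsinogen, at least 11.0-fold, the transcription factor SNAI2 at least 9.14-fold and KLK2 at least 8.14-fold. The related tripartite motif genes TRIM51 (4.24), TRIM49D1 (3.95), TRIM48 (3.64) and TRIM49D2 (3.62) also rose; their sequences are alike and their probes need not be independent.

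The largest decreases in control cells were in MMP16, a membrane-bound metalloproteinase (-2.65, SE 0.185), the cholesterol exporter ABCA1 (-2.61) and the opioid receptor OPRK1 (-2.56). COLCA1 changed by -2.46, LRRC31 by -2.34, ADM by -2.29, DDC by -2.20 and CBLN2 by -2.17.

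Of 34 measured androgen-induced genes, 30 rose and 0 fell in control cells (32 and 0 adjusted over the list alone), with a mean of 2.26 (adjusted p = 1.58e-52; adjusted p = 0.00408 with an estimated correlation), 2.43 in replicate 1 and 2.18 in replicates 2 and 3. In the mitosis list 17 of 29 rose (22 adjusted over the list alone; mean 0.48, adjusted p = 9.2e-13; adjusted p = 0.0233 with an estimated correlation), among them the kinesin KIF20A (0.79), the kinase AURKB (0.79) and the cyclin CCNA2 (0.77). Of the 5 HOXC genes, HOXC9 (-1.35), HOXC4 (-1.15), HOXC13 (-1.12) and HOXC8 (-0.83) fell, and all 5 did adjusted over the list alone (mean -0.96, adjusted p = 1.82e-06; adjusted p = 0.0238 with an estimated correlation; -1.03 in replicate 1 and -0.93 in replicates 2 and 3). Androgen-repressed genes fell in 9 of 17 cases and rose in 3, UGT2B28 (1.97) among them, with OPRK1, DDC and the neuronal leucine-rich repeat gene LRRN1 (-2.13) falling most. Adjusted over the list alone 3 rose and 11 fell. The mean was -0.82 (adjusted p = 5.25e-05; adjusted p = 0.0557 with an estimated correlation, and 0.0392 with the batch as a block besides).

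In lipid synthesis 10 of 25 genes rose and 1 fell, 15 and 1 adjusted over the list alone (mean 0.49, adjusted p = 2.79e-09; adjusted p = 0.0894 with an estimated correlation). The fatty acid elongase ELOVL5 rose by 1.67, the synthase FASN by 1.07 and the desaturase FADS1 by 1.03. In the folding list 5 rose and 3 fell, 10 and 3 adjusted over the list alone (mean 0.24, adjusted p = 0.000252; adjusted p = 0.0986 with an estimated correlation), led by the transcription factor CREB3L4 (0.89) and the chaperone DNAJB9 (0.80). Of the S phase genes 4 of 26 rose, 6 adjusted over the list alone (mean 0.31, adjusted p = 3.44e-05; adjusted p = 0.0557 with an estimated correlation), CDC45 (0.65) and FEN1 (0.52) among them. In the hypoxia list 6 rose and 2 fell, 7 and 2 adjusted over the list alone (mean 0.25, adjusted p = 0.00311; adjusted p = 0.0894 with an estimated correlation); ANKRD37 rose by 2.19 and the glucose transporter SLC2A1 by 0.80, and ADM fell. Of the p53 targets 4 fell, TP53INP1 (-1.47), SESN1 (-1.33), SPATA18 (-0.58) and the cell cycle inhibitor CDKN1A (-0.47), and 1 rose, the same numbers adjusted over the list alone (mean -0.33, adjusted p = 0.0326; adjusted p = 0.179 with an estimated correlation). This call was also lost without replicate 1 of the control cells in R1881 (adjusted p = 0.053), without their replicate 2 in ethanol (0.0509) and with a detection p under 0.01 on all arrays (0.087).

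B2M, a component of class I antigen presentation, rose by 0.90 among 11 housekeeping genes, and PGK1 and HPRT1 by 0.41 and 0.34 (list mean 0.18, adjusted p = 0.0343; adjusted p = 0.0894 with an estimated correlation). The housekeeping call was also lost without replicate 1 of the control cells in ethanol (adjusted p = 0.0513) or R1881 (0.053), without their replicate 3 in R1881 (0.0504), in replicates 2 and 3 only (0.0535), in the authors' values (0.0546), with the mean of probes (0.0742) and without the trend (0.0567). B2M kept its direction and call under each scaling, whereas PGK1 and HPRT1 lost their calls with median scaling (adjusted p = 0.108 and 0.118). Luminal identity genes included 4 that rose and 1 that fell; the transcription factor SPDEF rose by 1.85 and the keratin KRT8 by 1.73. That list's mean of 0.44 was not past the test (adjusted p = 0.085; 0.00703 with the batch as a block, lost at 0.06 with an estimated correlation besides). In the epithelial-mesenchymal list SNAI2, KRT19 (1.30) and TWIST1 (0.94) were among 5 that rose, and the metalloproteinase MMP10 (-0.95) was the 1 that fell (mean 0.43, adjusted p = 0.132). The interferon list had HERC5 higher (1.09) and UBE2L6 (-0.95) and MX1 (-0.79) lower, with a mean of -0.11 (adjusted p = 0.2). CDKN1A, also a published HOTAIR target, was the 1 change in that list (mean -0.25, adjusted p = 0.085), and 1 of 13 PRC2 and LSD1-CoREST components changed, PHF19 (0.79), whose 2 other detected probes had log2 values of 0.03 and -0.12 (list mean -0.06, adjusted p = 0.451). Means were -0.12 for lines without an androgen response (adjusted p = 0.451) and -0.01 for oxidative phosphorylation (0.998), with 0 genes changed. TUBB3 (-0.82) and ENO2 (-0.70) fell among 4 neuroendocrine genes. The single measured basal marker, DSC3, had differences of 0.23 to 0.28 in the 4 pairwise comparisons and passed the test in none.

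In control cells R1881 raised 558 genes and lowered 604, 188 and 134 by at least 2-fold. All 1162 kept their call and sign with the batch as a block, where 1381 were higher and 1736 lower; the replicate block gave 3220 genes and replicates 2 and 3 alone 2226. Without replicate 2 of the control cells in ethanol 774 genes were called.

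In HOTAIR cells, R1881 against ethanol asks which genes the androgen moves once HOTAIR is expressed. The androgen-induced list was again shifted upward, also with an estimated correlation, with a mean of 1.61 against 2.26 in control cells. FKBP5 rose by 2.64 (SE 0.16, adjusted p = 1.31e-06), KLK2 by 2.41, TMPRSS2 by 2.18 (SE 0.16) and KLK3 by 2.09 (SE 0.30, adjusted p = 0.000801). The largest increases were in the alpha-tubulins TUBA3E (3.57) and TUBA3D (2.92), in TRIM49D2 (2.92), TRIM48 (2.87), TRIM49D1 (2.86) and TRIM51 (2.84), and in SNAI2 (2.90) and TARP (2.87). The largest decreases were in OPRK1 (-2.32), the kinase inhibitor CAMK2N1 (-2.22), MMP16 (-2.06), ABCA1 (-2.01), the collagen COL5A2 (-2.01), the adaptor GRB10 (-1.96) and the phosphatase PTPRR (-1.90). LRRC31, undetected in R1881, was at least 3.93-fold lower.

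Androgen-induced genes rose in 26 of 34 cases in HOTAIR cells and fell in 0 (31 and 0 adjusted over the list alone), with a mean of 1.61 (adjusted p = 1.76e-47; adjusted p = 0.00577 with an estimated correlation), 1.77 in replicate 1 and 1.52 in replicates 2 and 3. HPGD (2.51) and the elongation factor EAF2 (2.41) were among them. Of 29 mitosis genes 7 rose (11 adjusted over the list alone), including BIRC5 (0.67) and CDC25C (0.65); the mean was 0.35 (adjusted p = 2.12e-09; adjusted p = 0.0568 with an estimated correlation). Both BIRC5 and CDC25C lost their calls with median scaling (adjusted p = 0.0582 and 0.0613). HOXC13 (-1.07), HOXC4 (-1.0) and HOXC9 (-0.73) fell, over all genes and adjusted over the list alone (list mean -0.60, adjusted p = 0.000805; adjusted p = 0.117 with an estimated correlation). Lipid synthesis genes rose in 8 of 25 cases, 13 higher and 1 lower adjusted over the list alone, with ELOVL5 at 1.68 and FASN at 0.98 (mean 0.38, adjusted p = 6.02e-08; adjusted p = 0.139 with an estimated correlation). In the folding list 5 rose, CREB3L4 (0.94) and MANF (0.54) among them, and 9 were higher and 2 lower adjusted over the list alone (mean 0.23, adjusted p = 0.000118; adjusted p = 0.139 with an estimated correlation).

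Androgen-repressed genes fell in 8 cases and rose in 3 in HOTAIR cells, 9 and 4 adjusted over the list alone (mean -0.56, adjusted p = 0.00993; adjusted p = 0.145 with an estimated correlation). With a detection p under 0.01 on all arrays the mean was -0.41 and not past the test (adjusted p = 0.244). OPRK1, CAMK2N1 and DDC (-1.74) fell and UGT2B28 (2.05) rose. Of the p53 targets 5 fell, TP53INP1 (-1.57) and SESN1 (-1.17) among them, and 1 rose, with the same counts adjusted over the list alone (mean -0.35, adjusted p = 0.00993; adjusted p = 0.145 with an estimated correlation). S phase genes had a mean of 0.21 (adjusted p = 0.00283; adjusted p = 0.139 with an estimated correlation); FEN1 (0.39) rose over all genes and 0 passed adjusted over the list alone. The HOXD cluster and other published HOTAIR targets had a mean of -0.29 (adjusted p = 0.0437; adjusted p = 0.139 with an estimated correlation), not past the test with the batch as a block (adjusted p = 0.0754), and CDKN1A (-0.47) was their 1 changed member. With no detection filter that mean was -0.06 (adjusted p = 0.553). The call was also lost with each scaling and background alternative (adjusted p = 0.0525 to 0.0621), and without replicate 1 (0.0668) or 2 (0.0686) in ethanol or 2 (0.0684) or 3 (0.0815) in R1881 of the HOTAIR cells. Luminal KRT8 (1.67) and SPDEF (1.48) rose (list mean 0.36, adjusted p = 0.0786; 0.00603 with the batch as a block, lost at 0.0715 with an estimated correlation besides). ACTA2 rose by 1.42, VIM fell by 0.62, and B2M rose by 0.80 among housekeeping genes (list mean 0.09, adjusted p = 0.264).

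Lists not past the test in HOTAIR cells included the epithelial-mesenchymal list, whose mean of 0.28 and median of -0.03 differed in sign (adjusted p = 0.398), and the hypoxia list, whose mean of 0.04 and median near 0 did too (adjusted p = 0.788). ANKRD37 rose by 2.08 and ADM fell by 1.53 in the latter. HERC5 (0.90) rose and UBE2L6 (-0.59) fell in the interferon list (mean -0.02, adjusted p = 0.734), although the other detected UBE2L6 probe had a value of 0.03. TUBB3 (-0.43) and ENO2 (-0.79) fell. Means were -0.02 for PRC2 and LSD1-CoREST components (adjusted p = 0.788), 0.01 for oxidative phosphorylation (0.663) and -0.07 for lines without an androgen response (0.697).

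In HOTAIR cells R1881 raised 387 genes and lowered 389, 147 and 83 by at least 2-fold. The batch block gave 1155 and 1479, among them all 776 genes, the replicate block 2694 and replicates 2 and 3 alone 1584. Median scaling gave 249 higher and 407 lower, and leaving out replicate 2 of the HOTAIR cells in ethanol gave 495 genes.

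**Figure D3:**
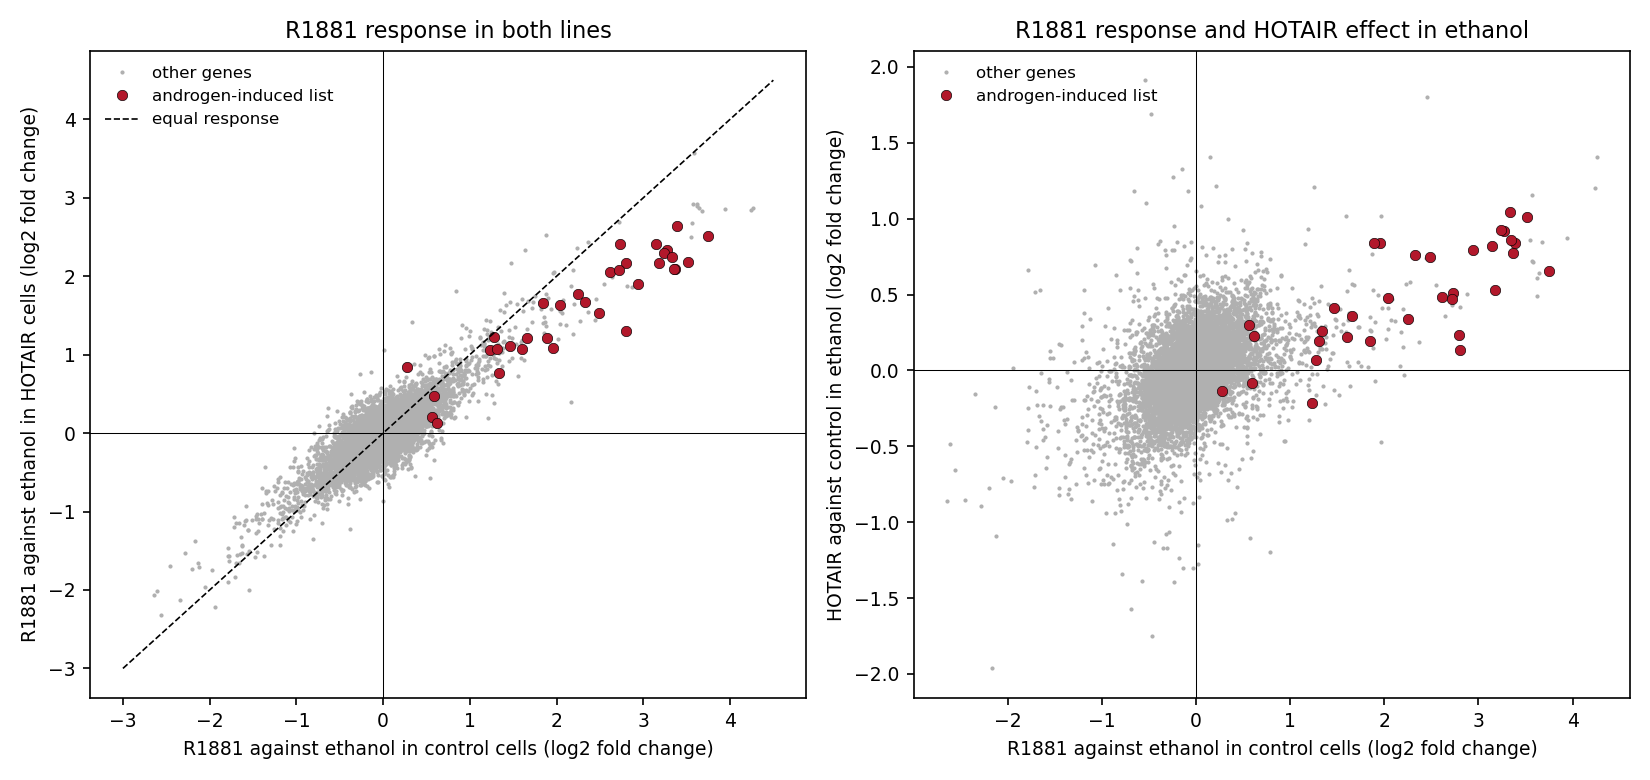
Log2 fold changes of the genes tested other than HOTAIR, each point a gene and the androgen-induced list in red. On the left the R1881 response in HOTAIR cells (y axis) is drawn against that in control cells (x axis) with a line of equal response, r = 0.857 with HOTAIR included; on the right the HOTAIR effect in ethanol (y axis) is drawn against the R1881 response in control cells, r = 0.467.

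Whether HOTAIR alters the androgen response was tested by the interaction of both factors. Across genes the R1881 responses of both lines were correlated (Pearson r = 0.857, Spearman 0.714; r = 0.814 in replicates 2 and 3), with a slope of 0.729 for HOTAIR on control cells. Raised in both lines were 338 genes, where independence would give 20.8, and lowered in both 310, where it would give 22.6, with 0 of opposite sign. For 238 of the 338 and 208 of the 310 the response was smaller in HOTAIR cells. Noise in the responses of control cells lowers the slope by itself, so 0.729 alone does not show a weaker response.

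For single genes limma called 0 interactions, with 303 at an unadjusted p under 0.05 and a smallest adjusted p of 0.142, for TARP and ERRFI1. With the batch as a block, an alternative added after the data were seen, 58 genes passed, 13 with a positive and 45 with a negative interaction, and 50 of them had an unadjusted p under 0.05 without the block. The replicate block gave 70 genes and replicates 2 and 3 alone 20. Of the 58, 14 were androgen-induced list members and 48 had a smaller response in HOTAIR cells. The most negative were ANGPT2 (-1.77), SPOCK1 (-1.50), TRIM51 (-1.40), TARP (-1.39), TMPRSS2 (-1.34, adjusted p = 4.56e-05) and ERRFI1 (-1.28), with KLK3 at -1.26 (adjusted p = 0.0128) and FKBP5 at -0.75 (adjusted p = 0.0325). The size for KLK3 leans on the array of control cells in ethanol on which it was undetected. ACTA2 (1.09) and IGFBP3 (1.02) were the most positive. KLK2 was not among them (adjusted p = 0.218); as it was undetected in control cells in ethanol, no size of its interaction is given, nor of that of HPGD.

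Of the gene lists, the androgen-induced one had the largest interaction, a mean of -0.65 with 33 of 34 members negative (adjusted p = 4.2e-35; adjusted p = 0.0157 with an estimated correlation), -0.66 in replicate 1 and -0.65 in replicates 2 and 3. None passed over all genes, and 18 were lower adjusted over the list alone. Its mean R1881 response was 2.26 in control and 1.61 in HOTAIR cells. Positive interactions were found for the HOXC cluster (0.36, adjusted p = 0.000201; adjusted p = 0.0734 with an estimated correlation) and androgen-repressed genes (0.26, adjusted p = 0.000201; adjusted p = 0.0863 with an estimated correlation), each with 1 member higher adjusted over the list alone. Negative ones were found for hypoxia (-0.21, adjusted p = 0.000158; adjusted p = 0.0734 with an estimated correlation), mitosis (-0.13, adjusted p = 0.00139; adjusted p = 0.219 with an estimated correlation) and S phase (-0.09, adjusted p = 0.0408; adjusted p = 0.253 with an estimated correlation), with 0 members past either adjustment. With the batch as a block and an estimated correlation, androgen-induced and androgen-repressed genes and hypoxia were past the test (adjusted p = 0.0362 each). Without replicate 1 of the control cells in ethanol the means were -0.07 for mitosis (adjusted p = 0.0677) and 0.17 for androgen-repressed genes (0.0677). The S phase call was lost without replicate 1 (-0.06, adjusted p = 0.171) or 2 (0.106) of the control cells in ethanol, 1 (0.101) or 3 (0.138) of the HOTAIR cells in ethanol, 3 of the control cells in R1881 (0.104) or 2 of the HOTAIR cells in R1881 (0.182). It was also lost with median scaling (adjusted p = 0.0806), cyclic loess (0.0566), the authors' values (0.0501), no detection filter (0.0906) and moderation without the trend (0.0543).

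Interactions of the remaining 11 lists did not pass, cholesterol and fatty acid synthesis coming closest (-0.11, adjusted p = 0.0592; 0.0293 with the batch as a block, lost at 0.453 with an estimated correlation besides).

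**Figure D4:**
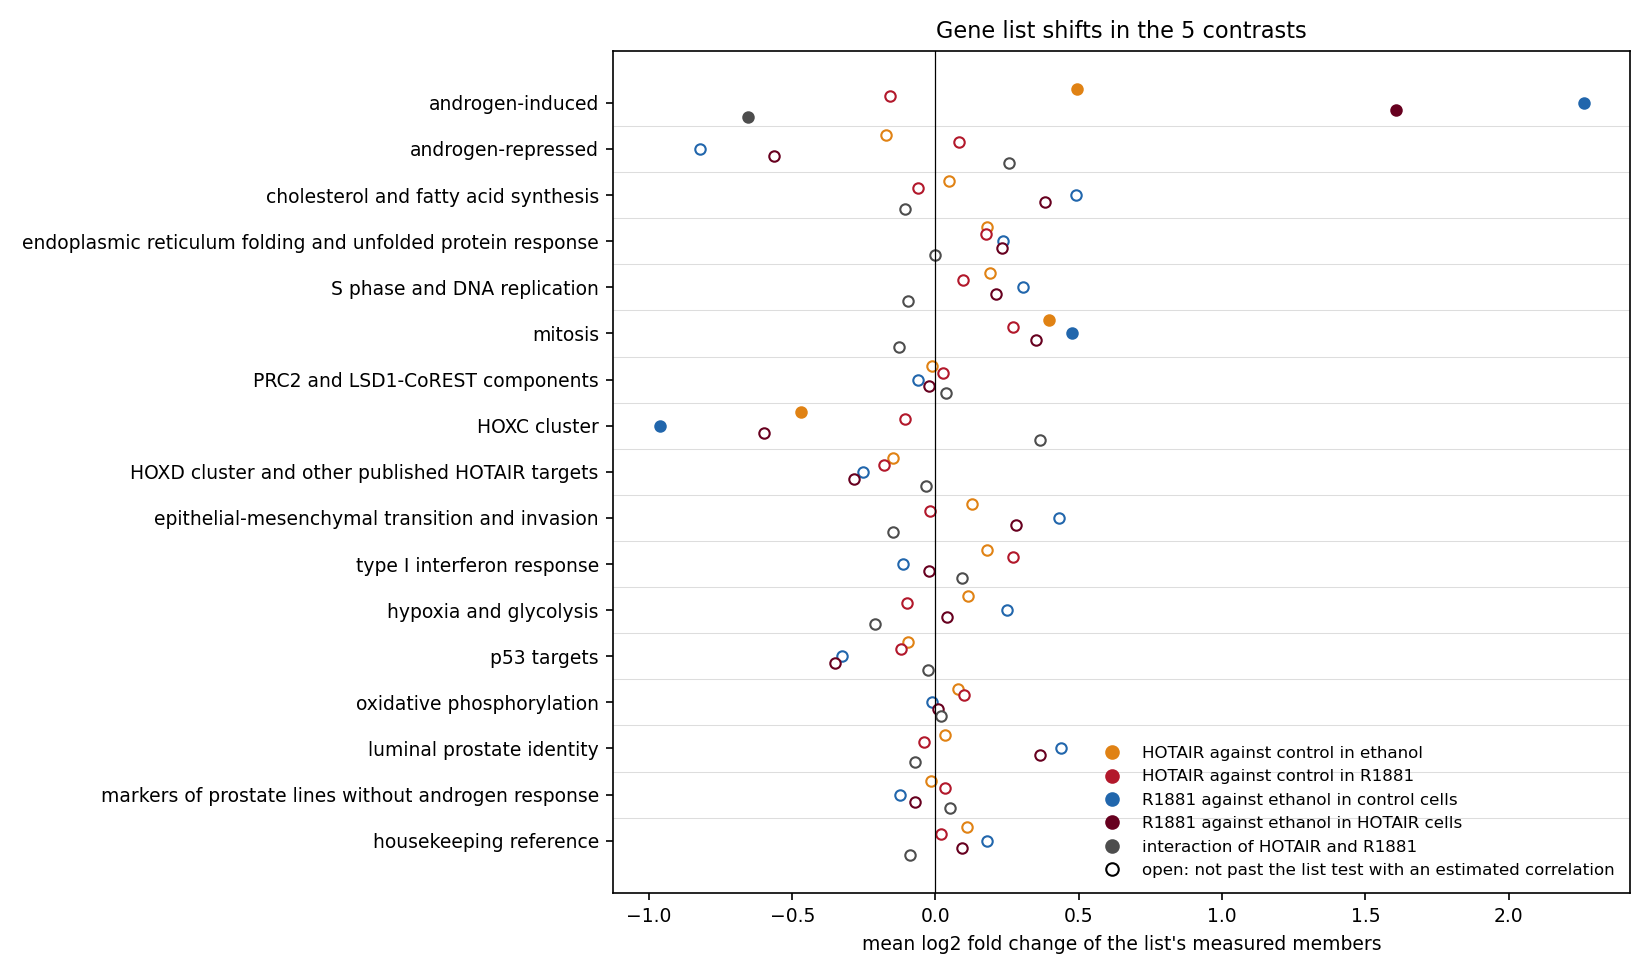
Mean log2 fold change (x axis) of the measured members of the 17 tested gene lists (y axis) in the 5 contrasts, by colour; filled points passed the list test with a correlation estimated from the data and open points did not. The androgen-induced list lies at 0.49 for HOTAIR in ethanol, -0.16 for HOTAIR in R1881, 2.26 and 1.61 for R1881 in control and HOTAIR cells, and -0.65 for the interaction.

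The last comparison asked whether HOTAIR without androgen moved the genes that androgen moves. Among the genes called, 31 were raised by both R1881 in control cells and HOTAIR in ethanol and 41 lowered by both, and 2 raised by R1881 were lowered by HOTAIR. Sharing arrays raises such overlaps, and the number that unchanged groups would give was not computed. TMPRSS2, FKBP5, NDRG1 and TARP were raised by both, and CBLN2, ADM, DDC and HOXC9 lowered by both. Across all genes r was 0.467 (Spearman 0.481; r = 0.497 in replicates 2 and 3). Both contrasts subtract the same 3 control arrays, which were too few to be split. In 200 simulations of unchanged groups sharing those arrays r averaged 0.499. The observed covariance was 0.0487, against 0.00816 simulated with the spread left after the replicate block, a difference of 0.0405; with the spread of the fit without a block the simulated covariance was 0.0236. Of the 387 genes that R1881 raised in HOTAIR cells, 75.5% had a positive HOTAIR effect in ethanol (median 0.16), and of the 389 it lowered 33.7% (median -0.11). These contrasts share the HOTAIR arrays in ethanol with opposite signs, which by itself would move both shares the other way.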

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

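Chosen only after the result was seen were the tests of the batch on the androgen-induced list, and of the batch and the pairing on the number of genes called, the fits with the batch as a block and on replicates 2 and 3 alone, and the grouping of the interaction splits by whether they mix both lines or keep the replicate 1 arrays together. The other tests in this part were planned before their results were seen.

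Androgen-induced genes responded less to R1881 in HOTAIR than in control cells, with a mean interaction of -0.654 on the log2 scale. They were higher with HOTAIR in ethanol but not in R1881. With an estimated correlation the shift in R1881, -0.16, was not past the list test (adjusted p = 0.432). The shift in ethanol lost its call with the batch as a block besides (adjusted p = 0.0886). A ceiling of the array's signal would spare dimmer genes. However, the 16 members below the 75th percentile in stimulated control cells had a mean interaction of -0.528, against -0.767 for the other 18. The SE of the former, 0.123, is over genes, which are not independent, and does not measure the spread between arrays. An effect of the replicate 1 batch is argued against by the shift in ethanol in replicates 2 and 3 alone, 0.516, and in replicate 1, 0.451. Among 32 swaps of HOTAIR and control labels within replicate number and treatment, 1, the real labelling, gave a mean interaction as large, a share of 0.0312 and the smallest that can be reached, the next being 0.58 in size. An effect of HOTAIR on the androgen response, with partial activity in the absence of added hormone, may account for the pattern, but other differences between the infected lines were not tested and stay open.

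Other lists were marked because the interaction test found a difference between both lines. The HOXC cluster had a mean interaction of 0.364 and androgen-repressed genes one of 0.258, falling less with R1881 in HOTAIR cells. Means were -0.212 for hypoxia and glycolysis, -0.127 for mitosis and -0.0946 for S phase and DNA replication. These 5 were not past the test with an estimated correlation (adjusted p from 0.0734 to 0.253). With the batch as a block besides, androgen-repressed genes and hypoxia were past it (adjusted p = 0.0362 each), and the other 3 were not.

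More genes were called in every contrast with the replicate number as a block. The batch alone lowered the median residual SD by 36.7% and gave at least 88.8% of the calls that the replicate number gave in each of the 4 simple contrasts (58 against 70 genes in the interaction), so the spread between the 2 batches may account for most of the gain. Pairing of the cultures beyond the batch is argued against by the difference between replicates 2 and 3, whose correlation between groups was at most 0.0904 (median 0.0528, 6 pairs of groups). No biological explanation was tested, because the labels give no property of the cultures that separates replicate 1.

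Other ways of dividing the arrays were counted for each result. The 6 arrays of a simple contrast make 10 splits into 3 and 3, too few for a share under 0.05. In gene counts, 1 split (the real one) reached the real value in each contrast, with 0 genes as the highest of the others against 136, 64, 1162 and 776 for HOTAIR in ethanol and in R1881 and for R1881 in control and in HOTAIR cells. Every other split mixes both groups, which puts any real effect into the spread within groups and lowers its count. These gene counts therefore cannot exclude chance. For gene lists past the test with the preset correlation the real value and the highest of the others were 7 and 8 for HOTAIR in ethanol (3 splits reached it), 6 and 4 for HOTAIR in R1881 (1 split), 10 and 10 for R1881 in control cells (2 splits) and 9 and 6 for R1881 in HOTAIR cells (1 split). In ethanol a split that set the replicate 1 arrays together gave 8 lists, and in control cells one gave 9. A fit with the batch as a block put 9 lists past the test in ethanol and 11 in control cells, the 7 and 10 among them. In replicates 2 and 3 alone 6 of the 7 and 9 of the 10 were past it.

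For the interaction 100 of 200 possible splits within each treatment were drawn. As the real count was 0 genes (limma, 303 at an unadjusted p under 0.05), all 100 had to reach it, and this count decides nothing. Of the others 8 called any gene. In 6 of these, with up to 343 genes, the real HOTAIR split of a treatment was kept. The highest, 1500 genes, points to a structure of the arrays. It kept the replicate 1 arrays of a treatment together, on opposite sides in ethanol and R1881, and gave 0 genes with the batch as a block, but only 2 of 7 such splits called any gene, so its cause stays open. As many lists as the real 6 were past the test in 16 of the 100, at most 8, and in 7 of the 81 that mixed both lines in both treatments, so chance is not excluded for the number of lists. Under the batch block 6 of the 100 gave at least the real 58 genes, at most 2158. The other 5 kept the real split in ethanol with R1881 labels mixed or reversed, which carries the HOTAIR effect itself into the interaction, so they are no reference without an effect. The 81 splits that mixed both lines in both treatments gave at most 1 gene with the block, which goes against chance. Mixing the lines also puts the HOTAIR effect into the spread within groups, however, which lowers such counts, so whether chance can be excluded for the 58 was left undecided.

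Probes without a gene name entered no comparison of the report and showed changes of their own. With HOTAIR 8 of 3802 such probes changed in ethanol and 13 in R1881. With R1881 248 changed in control cells (155 higher, 93 lower) and 186 in HOTAIR cells (126 higher, 60 lower).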

How the results depend on the processing

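The fits with the batch as a block, on replicates 2 and 3 only and on replicate 1 alone were chosen after the data were seen, and the others were planned. Of 243 results for named genes 178 were past the threshold, and 107 of these kept their call in all alternatives. Of 5396 alternative values 4791 kept direction and side of the threshold, 463 lost the threshold, 142 gained it and 0 were reversed. For the lists 38 of 85 results were past the test, and 8 with an estimated correlation.

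Counts of genes moved most with the block. With HOTAIR in ethanol, where 136 genes were called, there were 1243 with the batch block, 1334 with the replicate block, 507 in replicates 2 and 3 only, 460 with array weights and 1266 with the authors' processed values and the batch block. There were 70 with the authors' processed values alone, 89 with no detection filter and 27 with only the groups compared. With HOTAIR in R1881 (64) the batch block gave 894, the replicate block 1007, replicates 2 and 3 280, array weights 282 and the authors' values with the batch block 906. The authors' values and the detection p under 0.01 on all arrays gave 41 each, and only the groups compared 23. With R1881 in control cells (1162) these were 3117 (batch block), 3220 (replicate block), 2226 (replicates 2 and 3), 1966 (array weights) and 3147 (authors' values with the batch block). In HOTAIR cells (776) they were 2634, 2694, 1584, 1701 and 2628 in the same order, and 495 with only the groups compared. The interaction (0) gave 58, 70, 20, 10 and 58 in that order, and a fit on only the groups compared gives no interaction. Fewer arrays leave fewer degrees of freedom with only the groups compared, a block takes out the spread between batches, and the cause was not tested for the rest.

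The list shift of androgen-induced genes with HOTAIR in R1881, -0.16, was not past the test with an estimated correlation (adjusted p = 0.432) or with fry (adjusted p = 0.29). With R1881 in control cells it was 2.43 in replicate 1 alone, a value with no test. With the replicate block 34 results of named genes gained the threshold and 0 lost it. Lists that gained a call with it were oxidative phosphorylation and housekeeping genes for HOTAIR in ethanol (adjusted p = 0.0345 each), S phase (0.0342) and hypoxia (0.0446) for HOTAIR in R1881, luminal identity for R1881 in control (0.00644) and HOTAIR cells (0.00586), and cholesterol synthesis (0.0193) and housekeeping genes (0.0403) for the interaction. The HOXD cluster with other published targets lost its call for R1881 in HOTAIR cells (0.0731), and the replicate block changed no other list call. None of those that gained was past the test with the batch as the block and an estimated correlation (adjusted p = 0.06 to 0.501).

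Correlations across genes moved with the treatment of dim probes and with the replicates used. Between the HOTAIR effects r was 0.63 with no background correction, 0.475 with no detection filter, 0.485 in replicates 2 and 3 only and 0.425 in replicate 1 alone. Between the R1881 responses it was 0.899 with no background correction, 0.886 with an offset of 50, 0.805 with no detection filter, 0.829 with array weights, 0.814 in replicates 2 and 3 and 0.746 in replicate 1. Between the HOTAIR effect in ethanol and the R1881 response in control cells it was 0.577 over the genes changed by R1881 in HOTAIR cells, for which no value of unchanged groups was computed. The cause was not tested.

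Fits with 1 array left out had no block for the batch and left it uneven between the groups, so their losses can also carry the batch. Leaving out 1 array at a time gave 34 to 86 genes for HOTAIR in ethanol. In control cells these were 52, 34 and 86 without replicates 1, 2 and 3, and in HOTAIR cells 78, 58 and 34. In R1881 the range was 26 to 36, with 36, 27 and 35 without the control replicates and 36, 26 and 33 without the HOTAIR replicates. For R1881 it was 774 to 943 in control cells (774 without replicate 2 in ethanol) and 495 to 575 in HOTAIR cells (495 without replicate 2 in ethanol). The interaction gave 0 to 2 genes (2 without HOTAIR replicate 2 in ethanol), and the lists 34 to 39 calls. The androgen-induced shift ranged from 0.395 to 0.568 and from -0.222 to -0.0789 for HOTAIR in ethanol and R1881, from 2.18 to 2.32 and 1.53 to 1.71 for R1881 in control and HOTAIR cells, and from -0.728 to -0.555 for the interaction. In R1881 its call was lost without control replicate 1 (adjusted p = 0.186). The correlations ranged from 0.431 to 0.553, 0.785 to 0.849 and 0.393 to 0.528. Signal over background limits the dimmest genes, whose folds are lower bounds.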

Other observations

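The tests of gene families and of the batch on the interferon list in this part were chosen after the result was seen. The tests of the remaining interferon genes and of the selection of genes were planned before.

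Members of several gene families changed with HOTAIR. The families were chosen after their values were seen, and UGT2B11, UGT2B15, UGT2B17 and UGT2B28 also stand in the fixed androgen-repressed list and PCDHB5 among the published HOTAIR targets. AKR1C2 had differences of 1.91 in ethanol and 1.98 in R1881, which did not pass in limma (adjusted p = 0.186 and 0.245). With the batch as a block its adjusted p was 0.000111 and 0.000114. AKR1C3, which reduces steroid ketones, rose by 1.19 in ethanol (adjusted p = 0.0284). In R1881 the AKR1C3 difference of 1.11 did not pass (adjusted p = 0.0576, and 7.13e-05 with the batch as a block). UGT2B15 and UGT2B17, which inactivate androgens by glucuronidation, changed by -1.79 and -1.66 with R1881 in control cells, while UGT2B11 and UGT2B28 rose by 1.16 and 1.97. Of 4 VCX genes of the X chromosome, VCX (-1.23 and -1.25), VCX3A (-1.30 and -1.33) and VCX3B (-1.30 and -1.35) fell with HOTAIR in ethanol and R1881, and VCX2 had differences of -0.70 and -0.92 that did not pass in limma (adjusted p = 0.242 and 0.151; 0.00142 and 0.000124 with the batch as a block). OR51E2 changed by -0.84 in R1881, and OR51E1, undetected there in HOTAIR cells, was at least 1.90-fold lower without passing (adjusted p = 0.114; 0.00165 with the batch as a block). PCDHB2, a protocadherin, changed by -1.13 and -0.90. Probes of the AKR1C, UGT2B, VCX and KLK families, and of the TRIM48 and TUBA3 paralogs, can pick up related transcripts. AKR1C, UGT2B, VCX and OR51E members kept their sign under each scaling, whereas among 9 protocadherins in ethanol median scaling gave 3 positive and 6 negative differences, against 1 and 8.

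Whether these families shifted as a whole was left undecided, since the values of some members had prompted the question. The 4 AKR1C and UGT2B members other than AKR1C4, UGT2B10, UGT2B11 and UGT2B28 had a mean of 1.07 in ethanol and 1.28 in R1881, and UGT2B17 among them had already been named as rising. The 8 protocadherin beta members other than PCDHB5, PCDHB2 among them, had a mean of -0.37 in R1881 and -0.456 in ethanol, and 1 of 8 passed in each. With the batch as a block 3 of the 8 passed in R1881 and 4 in ethanol. Of the 4 AKR1C and UGT2B members 1 passed in each treatment without the block and 4 with it.

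The interferon list was shifted upward with HOTAIR in both treatments with the preset correlation, and was not past the test with an estimated correlation (adjusted p = 0.522 in ethanol and 0.432 in R1881). Whether the 2 genes past the test, IFIT1 and IFIT2, carry the list was tested without them. In R1881 the other 27 genes had a mean of 0.195 and still passed the list test of limma (adjusted p = 0.00484), whereas in ethanol they did not (adjusted p = 0.263). In R1881 an effect of the replicate 1 batch is argued against by a mean of 0.244 in replicates 2 and 3, against 0.327 in replicate 1. For ethanol the means were 0.144 and 0.249. Replicate 1 gave 1 array to each group, so a batch shift shared by the groups cancels in this comparison. With the batch as a block the list was past the camera test in ethanol (adjusted p = 0.0369), but not with an estimated correlation besides (0.234). The call was lost in replicates 2 and 3 alone (adjusted p = 0.0636). Without replicate 1 of the control cells the mean was 0.0854 (adjusted p = 0.347), but that omission unbalances the batch and cannot decide its part. Whether the shift in ethanol rests on replicate 1 stays open. Both HOTAIR and a response to the lentivirus that differs between the lines could account for the upward shift of the list, and neither was tested.

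A smaller R1881 response in HOTAIR cells might have come from choosing genes on their own noise. For 1032 genes chosen on replicates 2 and 3 by their mean response over both lines, the signed response in replicate 1 had a median of 0.854 in control and 0.739 in HOTAIR cells, a median difference of -0.128. Of the 512 raised genes 69.5% responded less in HOTAIR cells, and of the 520 lowered genes 60.6%. Genes chosen on other arrays thus kept a smaller response in replicate 1. However, replicate 1 is 1 array per group, and a shift of 1 array would move these genes together. Genes of an array are not independent, so the spread of the difference between arrays was not measured. Whether selection is the whole cause was left undecided.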
